A study of Homo sapiens with 24 samples.

How the data were processed

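Expression was measured on Affymetrix Human Genome U133 A oligonucleotide arrays in 6 established human lymphoma cell lines. L428, KMH2 and L1236 come from classical Hodgkin lymphoma, and Daudi, Namalwa and Raji come from Burkitt lymphoma. Each line was profiled on 2 untreated and 2 treated arrays, which gives 12 groups of 2 and 24 arrays in all. Groups, replicate numbers, drugs, doses and times were taken from the sample labels. Nothing in the labels says that the 2 arrays of a group came from separate cultures, so the p-values measure the spread between these arrays, which may be technical.

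The values used are linear probe set intensity values as the authors deposited them, 1 table of 22283 probe sets per array. They were made with GCOS, per the submitters' processing notes; its version, the signal algorithm and the scaling target are not given in the sources used here. In 22 of the 24 deposited tables the 2% trimmed mean of the 100 normalization-control probe sets was 2000, and it was 2800.73 on Namalwa untreated array 1 and 2234.32 on Raji treated array 2. The trimmed mean of all probe sets ran from 98.2 to 179 per array. The median signal ran from 30.6 to 55.7 on untreated arrays and from 48.5 to 85.8 on treated arrays. The 3' to 5' signal ratio was 0.789 to 1.03 for GAPDH and 0.903 to 1.28 for ACTB over the 24 arrays, and the 2 arrays of a group correlated at 0.924 to 0.968. No read depth applies to arrays, and their number limits the precision. Every deposited column was matched to a sample, so 0 columns were left out.

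Each array was scaled so that its trimmed mean over all probe sets (2% trimmed per side) was equal, the 68 control probe sets were left out, an offset of 10.44 was added and log2 was taken. The offset is the median over arrays of the 20th percentile of signal. A fold change is therefore on the log2(signal + offset) scale and understates the change of genes with low signal. Probe sets above the 40th percentile of their array on at least 2 arrays were kept. Gene names came from the annotation table supplied for the platform. It lists 19071 probe sets with 1 gene symbol, 1043 with several and none for 2169, controls included. The gene identifiers of 19059 of the 19071 were found in the reference gene table, and 0 symbols needed an update. Where several probe sets named 1 gene, the one with the highest mean log2 signal over the 24 arrays was used. Probe sets with several symbols or none were tested but not named. This gave 12399 tested features, of which 10189 are named genes and 2210 are not; all counts of genes below are of named genes, and the Benjamini-Hochberg adjustment ran over the 12399 features.

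All tests used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend) at an adjusted p of 0.05, and every adjusted p for a gene is limma's. The 24 arrays entered 1 fit with 12 group means and 12 residual degrees of freedom. The treatment change of a lymphoma type is the mean over its 3 lines of treated minus untreated, so its error is the spread between duplicate arrays and the result is about these 3 lines. The difference between the types' changes was tested as a contrast in the same fit. Untreated Hodgkin and Burkitt lines were compared after averaging the 2 arrays of a line, 3 lines against 3, with 4 residual degrees of freedom. The error given for a gene is the moderated standard error (SE) of its contrast. For gene lists, limma's camera was run with a preset inter-gene correlation of 0.01, adjusted over the 26 lists of a comparison, and again with an estimated correlation; it compares the list with all other genes. Files were read with jsonlite 2.0.0 and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

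The 26 gene lists, the rule for naming genes and the first set of alternatives below were fixed before the data were examined; the lists came from general knowledge. The lists cover B-cell identity, germinal centre, MHC class II, MHC class I, Hodgkin-characteristic, T-cell and NK, myeloid and dendritic, plasma cell, erythroid and megakaryocyte, epithelial and stromal, neuronal, cancer-testis, imprinted, interferon-stimulated, NF-kB target, AP-1 and immediate early, p53 and DNA damage, histone and deacetylase-inhibitor response, methylation and acetylation machinery, cell cycle, MYC and ribosome biogenesis, ribosomal protein, unfolded protein response, cholesterol synthesis, metallothionein and apoptosis genes. Some genes stand on more than 1 list. The rule names the 8 largest rises and 8 largest falls past the threshold that had the same direction in all 3 lines (for the untreated comparison, with all lines of a type above all of the other), up to 4 members of each described list by size of change, the 3 largest changes per direction in each line, the 5 largest per direction for the difference between the types' changes, and a set of B-cell and Hodgkin genes that was always given where measured. Genes of that set or of the lists that the annotation table does not list are not analysed here.

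Experiment records deposited with the arrays hold the scan day of most arrays, chip lots and processing stations. Scan days were coded as 12 days and divided at their longest gap into an early and a late period, a division chosen after the records had been seen. All 6 untreated Hodgkin arrays and 4 of the 6 untreated Burkitt arrays were early; Namalwa untreated array 2 and Raji untreated array 2 were late. The day of Daudi untreated array 2 could not be read, and its chip lot placed it in the early period. Of the treated arrays, 11 were late and Raji treated array 2 had no record. A fit with the period as a term is therefore estimated only through the 2 late untreated arrays. The day that held Namalwa treated array 2, Namalwa untreated array 2 and Raji untreated array 2 was the only one with treated and untreated arrays.

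The first set of alternatives was quantile and cyclic loess normalization, offsets of 1 and at the 40th percentile, no filter and a filter at the 60th percentile, the mean of a gene's probe sets, eBayes without trend, a test against a fold of 1.5 (limma's treat), each array or line left out in turn, a replicate block, the line as a random block or as the replicate, the scan day as a block and, for correlations, split controls. Those added afterwards were the period term, early arrays only, late arrays only of Namalwa and Raji, scaling on the 100 normalization-control probe sets, and leaving out 3 doubted arrays: Raji treated array 2, Namalwa treated array 1 (the 2 with the highest CreX spike-in signal over the array's trimmed mean) and L1236 treated array 1, whose record notes scratches.

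The procedure was tested on simulated arrays with 200 planted changes. For the treatment of 3 lines it recovered 38.8% of changes of 1.5-fold, 91% of 2-fold and 100% of 4-fold, with 8 calls among 9989 unplanted genes. For the untreated comparison of 3 lines against 3 it recovered 76.1% of changes of 4-fold, 92.5% of 8-fold and 98.5% of 16-fold, with 10 calls among 9989. A planted list of 40 genes was recovered, and 1 of the 26 lists with nothing planted passed the threshold. The simulated noise was independent between genes and held no scan-period effect. These rates therefore do not cover lists of genes that vary together or differences between scan periods.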

Results

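The series asks how epigenetic regulation bears on the B-cell programme of classical Hodgkin lymphoma, a B-cell tumour that has switched off most B-cell genes. Hodgkin lines (L428, KMH2, L1236) were given the DNA methyltransferase inhibitor 5-aza-dC at 5 µM for 5 days. Burkitt lines (Daudi, Namalwa, Raji) were given 5-aza-dC for 6 days plus the histone deacetylase inhibitor TSA at 625 nM for the last 24 h; the sample labels give 5 µM of 5-aza-dC for them and the series text gives 3 µM. Each line had 2 untreated and 2 treated arrays (12 groups, 24 arrays), and 10189 named genes were tested. Drug, days of treatment and lymphoma type changed together, so no difference between the types' responses can be assigned to 1 of them. Nearly all treated arrays were scanned in a later period than the untreated arrays, so list counts with a term for that period are given beside the others ("period term", members up and down). For genes the term is named where it ended a call. For gene lists, counts are of members past an adjusted p of 0.05 over all genes; a count adjusted over the list alone is given where it differs.

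Untreated Hodgkin lines had far lower signal of the B-cell receptor chains and of the kinase SYK than Burkitt lines, and higher signal of LGALS1, BATF3 and CCND2. The largest difference was in galectin 1, LGALS1, a secreted lectin typical of Hodgkin cells, which was higher in Hodgkin lines (log2 difference 7.03, SE 0.33, limma adjusted p = 0.00082, n = 3 lines per type). Its signal was 1410 to 2700 in the 3 Hodgkin lines and 3.06 to 9.33 in the 3 Burkitt lines (means of 2 arrays). The latter lie under the offset of 10.44, so the log2 differences of LGALS1 are set in part by the offset and give no exact fold. The B-cell receptor chains CD79A (-4.88, SE 0.38) and CD79B (-4.66, SE 0.24) and the kinase SYK (-4.94, SE 0.19, limma adjusted p = 0.0005) were lower in all 3 Hodgkin lines than in any Burkitt line. The immunoglobulin genes IGHM (-5.76, SE 0.34) and JCHAIN (-6.09, SE 0.35) and the B-cell surface gene MS4A1 (-5.06, SE 0.28), which encodes CD20, were lower too.

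In all, 73 genes were higher and 82 lower in Hodgkin lines, and 142 genes passed on early arrays only. Other genes higher in Hodgkin lines were the AP-1 partner BATF3 (5.87, SE 0.49), the cyclin CCND2 (5.53), the imprinted gene PHLDA2 (5.12), the keratin KRT7 (4.81) and the T-cell factor GATA3 (4.61, SE 0.41, limma adjusted p = 0.005). Among the lower ones were PLAC8 (-4.97) and CD38 (-4.88). The actin bundler FSCN1 was higher by 5.88 (limma adjusted p = 0.01; 5.56 and 0.0584 without Daudi), and the heat shock gene HSPB1 by 6.00 (0.016; 0.086, 0.0644 and 0.0615 without Daudi, Namalwa or Raji). PRDX2 was lower (-5.03; -5.04 with limma adjusted p = 0.0566 without Daudi, -2.14 and 0.0615 as the mean of its probe sets). The B-cell identity list moved as a whole: 0 of 42 measured members were higher and 11 lower (28 lower adjusted over the list alone; mean -2.41, camera adjusted p = 2.68e-25, 0.0287 with an estimated correlation). Of 17 germinal centre genes 5 were lower (7 alone; mean -1.74, 5.63e-08, 0.0621 with an estimated correlation). Of 48 Hodgkin-characteristic genes 10 were higher and 0 lower (24 higher alone; mean 2.06, 6.55e-20, 0.04 with an estimated correlation). On the day that held 3 Hodgkin arrays and 1 Daudi array, 36 of 42 B-cell identity genes were lower in the Hodgkin arrays (mean -2.48), and on the day with 1 KMH2 and 1 Namalwa array 39 were (mean -2.56).

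Upstream B-cell regulators were less uniform. L1236 kept PAX5 (signal 473, beside 38.4 in L428 and 58.9 in KMH2) and POU2AF1 (1080, beside 22.6 and 23.7). The differences of PAX5 (-2.32, limma adjusted p = 0.32), the coactivator POU2AF1 (-4.14, 0.25), SPIB (-2.77, 0.25), BLNK (-2.79, 0.16) and TCF3 (-0.92, 0.39) did not pass over 3 lines per type. Without L1236, PAX5 was lower by -3.35 (limma adjusted p = 0.0209) and POU2AF1 by -5.82 (0.00196). The Hodgkin marker TNFRSF8, which encodes CD30, differed by 2.56 (limma adjusted p = 0.11; 3.18 and 0.0233 without L1236), the repressor MSC by 2.78 (0.061; 2.83 and 0.0498 without Daudi untreated array 2) and ID2 by 1.42 (0.36). No difference passed for NOTCH1 (-0.02), CSF1R (0.94), POU2F2 (-0.14) or the methyltransferase DNMT1 (-0.26). On the 12 arrays with the line as a random block 6 of these genes passed by limma: PAX5 (0.0356), POU2AF1 (0.0114), SPIB (0.0231), BLNK (0.00588), TNFRSF8 (0.00274) and MSC (0.000321). With a replicate block added the last 5 passed (0.000762 to 0.0313). The first of these fits gave all genes 1 within-line correlation of 0.59, and both count duplicate arrays as partly separate. Where the lines of a type differ as much as for POU2AF1, the p-values of such fits can be too small. The count of 155 genes fell to 62 without Daudi, 97 without Namalwa and 100 without L428, and 3 lines per type limit this comparison to large differences.

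**Figure D1:**
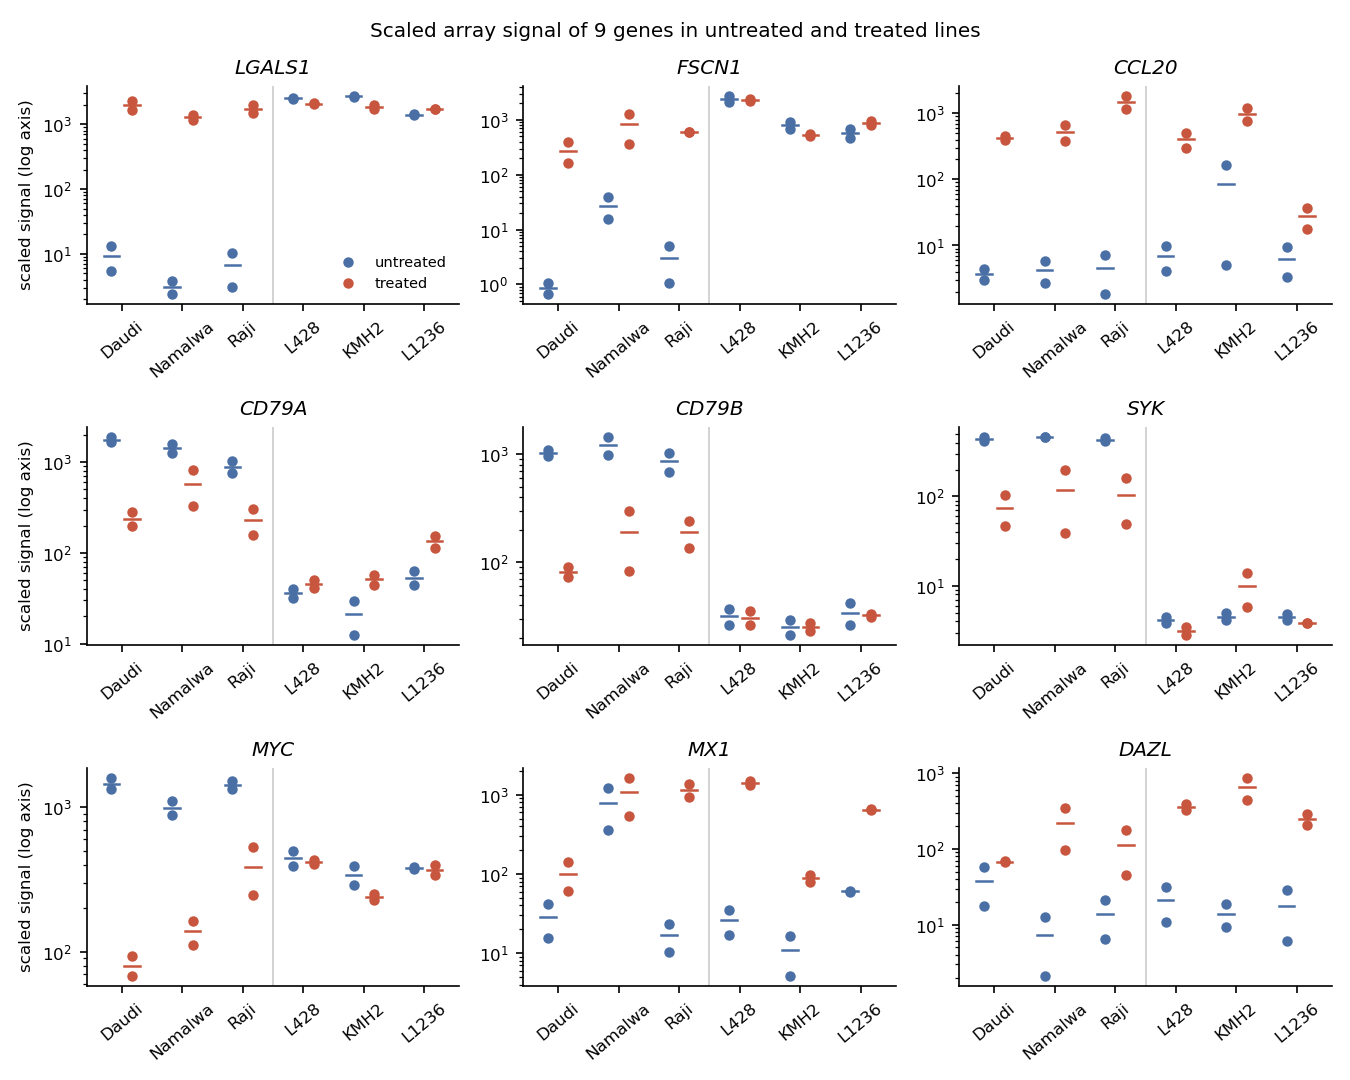
Scaled signal (log axis) of 9 genes in the 6 lines, untreated and treated; each point is 1 array and each bar is the mean of 2. LGALS1 went from 9.33 to 1960 in Daudi and CD79A from 1770 to 239.

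Treated Burkitt lines gained genes typical of Hodgkin cells and lost B-cell receptor genes. LGALS1 rose (log2 change 6.65, SE 0.13, limma adjusted p = 2.46e-19, 3 of 3 lines, n = 6 arrays per condition), from a mean log2 signal of 4.03 to 10.68, beside 11.06 in untreated Hodgkin lines. The chemokine CCL20 (5.57, SE 0.38), FSCN1 (4.79, SE 0.24) and the dendritic-cell gene LAMP3 (4.63, SE 0.25) also rose in all 3 lines. CD79B fell (-2.82, SE 0.23, limma adjusted p = 3.1e-09), as did CD79A (-2.08, SE 0.21), SYK (-2.28, SE 0.29) and the adaptor BLNK (-1.87, SE 0.24). MYC, which the Burkitt translocation drives, fell by 2.92 (SE 0.16, limma adjusted p = 7.8e-12).

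Over the 3 lines 3820 genes rose and 1931 fell, 1264 and 626 of them by at least 2-fold. With the period term 3121 genes passed (1859 up, 1262 down), 3030 of them shared with the same sign. The share that rose was 66.4%, and 51.0% with quantile, 56.1% with loess and 77.8% with normalization-control scaling; the median change of all genes was 0.28, -0.00, 0.04 and 0.43 in these scalings. Further large rises were in DHRS2 (5.51), TKTL1 (5.17), CCNA1 (4.85) and NPTX2 (4.30), genes best known from metabolism, germ cells and neurons, and further falls in MZB1 (-3.39), PTPRCAP (-3.05), PVRIG (-3.03), the coactivator POU2AF1 (-2.90), RANBP1 (-2.78) and SIT1 (-2.50).

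Of 42 B-cell identity genes 3 rose and 25 fell (27 fell adjusted over the list alone; mean change -0.94, camera adjusted p = 7.41e-10, 0.0469 with an estimated correlation; 1 and 21 with the period term). Falls included TNFRSF17 (-2.49), TCL1A (-2.37), TCF3 (-1.24) and the master regulator PAX5 (-0.96, SE 0.17, limma adjusted p = 5.7e-05). MS4A1 fell as well (-0.90, limma adjusted p = 0.0024), though not with the period term (0.0824) or without Daudi (-0.47, 0.21), and POU2F2 (0.28, 0.17) did not pass. By limma POU2F2 passed with normalization-control scaling (0.44, 0.0297), and as the mean of its probe sets it passed in the other direction (-0.42, 0.0427). SPIB did not pass (0.38, limma adjusted p = 0.066) but did without Daudi (0.71, 0.013), Daudi treated array 2 (0.46, 0.0446), Raji untreated array 1 (0.49, 0.0275) or an untreated KMH2 array (0.0137 and 0.0136). It also passed with quantile (0.62, 0.00585), loess (0.72, 0.00178) and normalization-control scaling (0.57, 0.0126). Of 17 germinal centre genes 3 rose and 9 fell (10 alone; mean -0.76, 0.000461, 0.0598 with an estimated correlation, 2 and 6 with the period term), with MME (-2.44) and BCL7A (-1.99) in front. Of 48 Hodgkin-characteristic genes 39 rose and 1 fell (42 rose alone; mean 1.48, 7.41e-10, 0.000705 with an estimated correlation; 30 and 1 with the period term). This list held CCL5 (4.18), which recruits T cells, CSF1R (2.57, a myeloid receptor) and ID2 (2.09, an inhibitor of E proteins). It also held GATA3 (1.48), NOTCH1 (1.02) and TNFRSF8 (0.78). MSC did not pass (0.12, 0.55 by limma) except without Daudi (0.57, 0.0217). Members such as CCL5, CCL20 and JUN also stand on the NF-kB target or AP-1 lists, so the rises of these lists are not separate results. Weak genes rose in general in treated Burkitt lines (correlation of the change with the untreated Burkitt level -0.507). No random lists of matched level were drawn for this list.

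NF-kB target and immediate early genes rose in treated Burkitt lines, while cell cycle and MYC-related genes fell. Of 35 NF-kB target genes 26 rose and 2 fell (mean 1.65, camera adjusted p = 2.79e-08, 0.00726 with an estimated correlation, 26 and 1 with the period term), among them CXCL10 (3.96) and TNFAIP2 (3.46). Of 30 AP-1 and immediate early genes 22 rose (23 alone) and 1 fell (mean 1.12, 1.92e-05, 0.031 with an estimated correlation, 15 and 1 with the period term), led by JUN (3.15), DUSP1 (3.02) and FOS (2.63). Interferon-stimulated genes rose in 37 of 43 cases and fell in 1 (mean 1.72, 8.88e-10, 0.139 with an estimated correlation, 28 and 1 with the period term), for example IFI27 (3.06), RIGI (2.98) and IRF7 (2.91). Of 33 MYC and ribosome biogenesis genes 1 rose and 29 fell (mean -1.18, 6.37e-19, 0.000735 with an estimated correlation, 1 and 25 with the period term), among them MRTO4 (-2.45), PA2G4 (-2.15) and SRM (-2.11). Of 52 cell cycle genes 5 rose and 36 fell (mean -0.68, 1.18e-12, 0.0312 with an estimated correlation, 2 and 27 with the period term), with TYMS (-2.44), CDC25A (-2.25) and CCNA2 (-1.80). Cancer-testis genes, a class often silenced by DNA methylation, rose in 21 of 29 cases (mean 1.26, 3.05e-05, 0.0818 with an estimated correlation, 14 and 0 with the period term), among them MAGEA6 (2.83) and SSX1 (2.52).

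In each Burkitt line LGALS1 rose from a signal under the offset (9.33 in Daudi, 3.06 in Namalwa, 6.70 in Raji) to 1960, 1290 and 1750. Differences between lines were not tested for lists, and the list values below are per line. Interferon-stimulated genes rose in Raji (43 of 43, mean 2.82, camera adjusted p = 2.74e-28, 0.0314 with an estimated correlation, 35 and 0 with the period term) and Namalwa (35 up, 0 down, mean 2.36, 9.62e-14, 0.075 with an estimated correlation, 29 and 0 with the period term). In Daudi 11 rose and 9 fell (mean -0.04, 0.0764), but 4 rose and 18 fell with the period term (mean -0.96). The untreated Daudi arrays were already at 7.71 and 7.75 in this list, beside 6.31 and 6.37 on the early untreated Namalwa and Raji arrays. Daudi had no late untreated array. Its value with the period term thus takes over the late minus early difference of Namalwa and Raji (0.922) and does not show a fall in Daudi. Cell cycle genes fell in Namalwa (44 of 52, 46 alone, mean -1.48, 3.85e-28, 0.00237 with an estimated correlation, 0 and 44 with the period term), and in Raji 12 rose and 17 fell (13 and 18 alone, mean -0.06, 0.219), but 10 rose and 1 fell with the period term (mean 0.14). The largest falls were MZB1 (-4.70), ID3 (-4.25) and POU2AF1 (-4.23) in Daudi, GPR18 (-3.83), PTPRCAP (-3.58) and RANBP1 (-3.27) in Namalwa, and BDH1 (-2.74), RGS13 (-2.61) and JCHAIN (-2.57) in Raji. RGS13 did not pass with the period term (-1.10, limma adjusted p = 0.446) or without Raji treated array 2 (-1.92, 0.152). The response differed between the 3 lines for 1270 genes (limma F test). Genes changed numbered 4036 in Daudi, 3663 in Namalwa and 2414 in Raji (1175 without Raji treated array 2, 1438 without Raji untreated array 1; 2195, 3154 and 966 with the period term). Raji treated array 2 had no experiment record and a CreX spike-in signal 52.09 times its trimmed mean (other arrays 12.2 to 28.8). The fit with the period term also took this array out of the Raji change. Losses of Raji calls in that fit therefore cannot be assigned to the scan period alone.

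**Figure D2:**
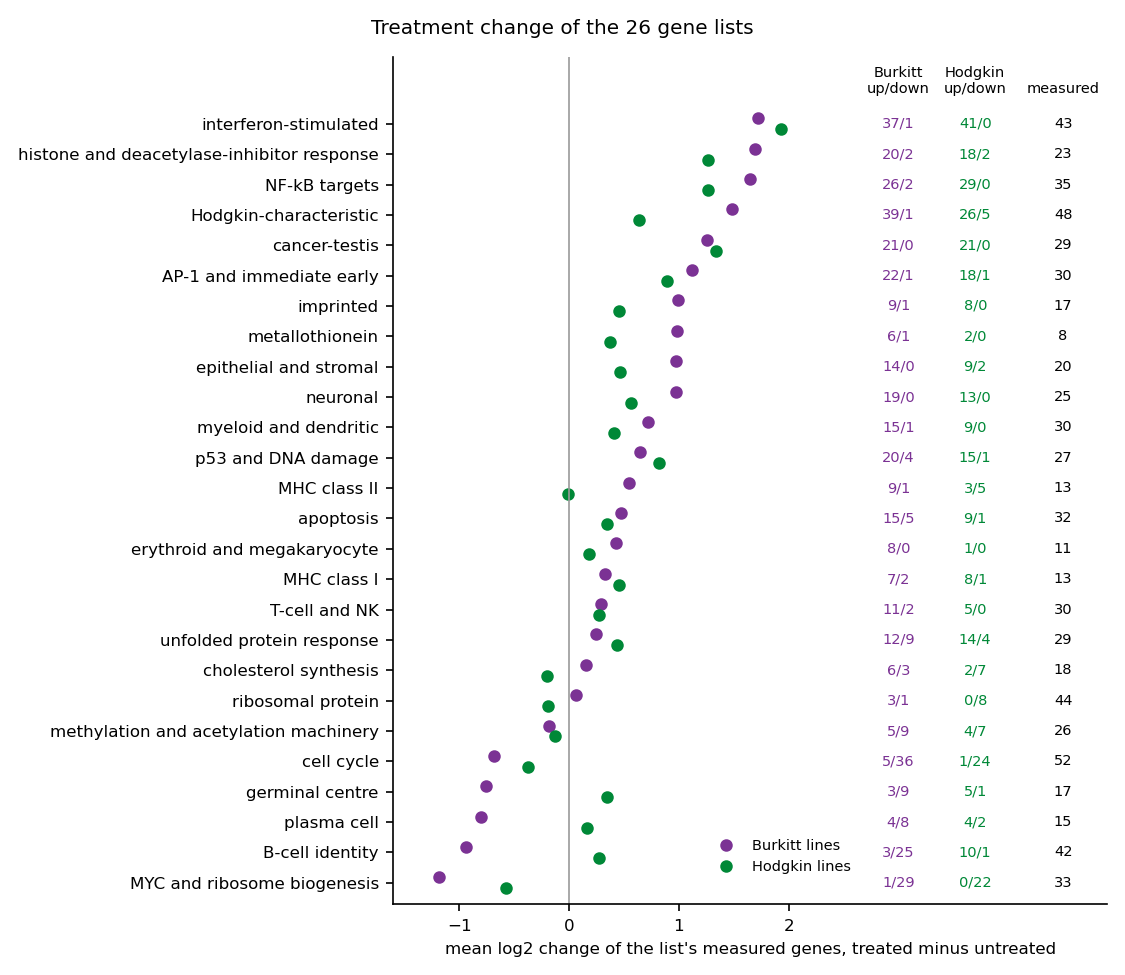
Mean log2 change on treatment (x axis) of the 26 gene lists in Burkitt and Hodgkin lines; numbers at the right are members up/down and members measured. The B-cell identity list had 3 of 42 members up and 25 down in Burkitt lines and 10 up and 1 down in Hodgkin lines.

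Treated Hodgkin lines had higher signal of interferon-stimulated, NF-kB target and cancer-testis genes. Treatment and scan period coincided in these lines, so none of these rises can be fully separated from the period. The late minus early difference, known only from untreated Namalwa and Raji arrays, was 0.922, 0.0703 and 0.29 for these 3 lists in turn. The scan period could thus explain part or all of the interferon-stimulated rise. The B-cell identity list did not pass as a whole. IFI27 (5.46, SE 0.43, limma adjusted p = 8.8e-09, 3 of 3 lines, n = 6 arrays per condition) and MX1 (3.60, SE 0.30), both classical interferon targets, rose. The chemokine CCL22, which Hodgkin cells secrete, rose by 4.43 (SE 0.23, limma adjusted p = 7e-11), and CCL20 rose by 3.31 (SE 0.38). TKTL1 (4.49, SE 0.23), the germ-cell gene DAZL (3.90, SE 0.35) and the polyamine enzyme SAT1 (3.32, SE 0.13) rose in all 3 lines.

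Over the 3 lines 2103 genes rose and 1362 fell, 646 and 143 by at least 2-fold, and with the period term 835 passed (474 up, 361 down; 766 shared with the same sign). The share that rose was 60.7%, and 51.5% with quantile and 86.0% with normalization-control scaling (median change 0.08, -0.03 and 0.30). All untreated Hodgkin arrays were early and all treated ones late, so no scan period held both. Falls were smaller: PFAS (-2.12, SE 0.18) of purine synthesis, SIVA1 (-1.81), PRMT7 (-1.59), RITA1 (-1.58), GPI (-1.53), WDR18 (-1.50) and MRPS34 (-1.48).

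Of the B-cell identity list 10 of 42 genes rose and 1 fell (mean 0.27, camera adjusted p = 0.113, 0.55 with an estimated correlation, 6 and 1 with the period term). The mean was 0.14 with quantile scaling (8 up, 2 down) and 0.46 with normalization-control scaling (16 up, 0 down). SPIB rose (1.98, SE 0.17, limma adjusted p = 3.6e-08), as did CXCR5 (2.04), CD24 (1.66) and FCGR2B (1.15). CD79A rose by 0.82 (limma adjusted p = 0.0046; 0.217 with the period term; 0.64 and 0.0842 without L1236), to signals of 45.4 to 134 beside 891 to 1770 in untreated Burkitt lines. PAX5 rose by 0.68 (0.0034 by limma; 0.0957 with the period term; 0.53 and 0.076 without L1236), and TCF3 fell by 0.48 (0.0031 by limma; 0.279 with the period term; -0.39 and 0.0772 without L428). As the mean of its probe sets neither passed (PAX5 0.32, 0.221 by limma, TCF3 -0.18, 0.233), nor did TCF3 with loess (0.0582) or normalization-control scaling (0.174). CD79B (-0.02), MS4A1 (-0.37), SYK (0.08), BLNK (-0.24) and POU2F2 (-0.02) did not pass, nor did the Hodgkin genes CSF1R (0.11) and MSC (-0.13). POU2AF1 (-0.71, limma adjusted p = 0.061) passed without L428 (-1.08, 0.0397), KMH2 (-0.98, 0.0485), Namalwa (0.00809), Raji (0.0442) or any 1 treated Namalwa or Raji array (0.00613 to 0.0397). It also passed with quantile scaling (-0.85, 0.0418), a replicate block (0.0405) and without the 3 doubted arrays (-0.80, 0.000224). By limma GATA3 (0.26) did not pass but did without KMH2 (0.40, 0.0392) or its treated array 1 (0.40, 0.0292), NOTCH1 (0.44) did so without L1236 untreated array 2 (0.60, 0.0287) and TNFRSF8 (-0.21) without L1236 (-0.64, 0.00763). With normalization-control scaling GATA3 (0.52, 0.00726) and NOTCH1 (0.66, 0.0173) passed, and GATA3 did with quantile scaling (0.48, 0.01). ID2 rose (1.36). Of the 17 germinal centre genes 5 rose and 1 fell (mean 0.34, 0.138, 5 and 0 with the period term), with SWAP70 (1.31) and BCL6 (1.18). Of the 48 Hodgkin-characteristic genes 26 rose and 5 fell (8 fell alone; mean 0.64, 0.000712, 0.0161 with an estimated correlation; 13 and 4 with the period term).

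Interferon-stimulated genes rose in 41 of 43 cases (42 alone; mean 1.93, camera adjusted p = 1.72e-24, 0.0339 with an estimated correlation), and 14 rose and 2 fell with the period term (mean 1.00). The late untreated arrays of Namalwa and Raji lay above the early ones in this list by 0.52 and 1.32. Of 35 NF-kB target genes 29 rose (mean 1.27, 5.14e-14, 0.00164 with an estimated correlation; 17 with the period term), such as IER3 (2.94) and IL6 (2.44). Cancer-testis genes rose in 21 of 29 cases (mean 1.34, 1.68e-10, 0.026 with an estimated correlation; 10 with the period term), with MAGEA6 (3.25) and MAGEA12 (2.51). Of 27 p53 and DNA damage genes 15 rose and 1 fell (mean 0.82, 2.51e-06, 0.00164 with an estimated correlation, 9 and 0 with the period term), among them GDF15 (3.06), GADD45A (2.97) and CDKN1A (2.40). Of 33 MYC and ribosome biogenesis genes 0 rose and 22 fell (23 alone; mean -0.57, 1.1e-12, 0.00341 with an estimated correlation, 0 and 11 with the period term), and of 52 cell cycle genes 1 rose and 24 fell (28 alone; mean -0.38, 4.71e-09, 0.0509 with an estimated correlation, 1 and 11 with the period term). With normalization-control scaling 1 MYC and ribosome biogenesis gene rose and 12 fell (mean -0.33), and 5 cell cycle genes rose and 10 fell (mean -0.13).

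Of the genes changed over the 3 Hodgkin lines, 194 passed upwards and 134 downwards in each of the 3, and the response differed between the lines for 655 genes (limma F test). L428 raised IFI27 (6.27), TKTL1 (5.69) and SSX1 (5.50) most, KMH2 raised GDF15 (5.27), IFI27 (4.95; 2.47 with limma adjusted p = 0.076 with the period term) and RRAD (4.79), and L1236 raised IFI27 (5.15), TFPI2 (4.66) and TRIM29 (4.65). The largest falls were BCL7C (-2.77), GPR25 (-2.57) and PYCR3 (-2.41) in L428, PRG4 (-2.79), GKN1 (-2.37) and SIVA1 (-2.22) in KMH2, and DCXR (-2.75), ALOX15 (-2.74) and PFAS (-2.71) in L1236. GKN1 did not pass with the period term (-2.16, limma adjusted p = 0.12) or without KMH2 treated array 2 (-1.53, 0.122) or untreated array 2 (-1.88, 0.0902). Cancer-testis genes rose in 20 of 29 cases in L428 (21 alone, mean 2.17, 13 with the period term), 7 in KMH2 (11 up and 1 down alone, mean 0.74, 3 with the period term) and 11 in L1236 (13 alone, mean 1.10, 5 with the period term). Genes changed numbered 1914 in L428 (968 to 1257 when 1 of its arrays was left out), 1235 in KMH2 (573 to 727) and 1870 in L1236 (951 to 1170), and 876, 400 and 774 with the period term.

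**Figure D3:**
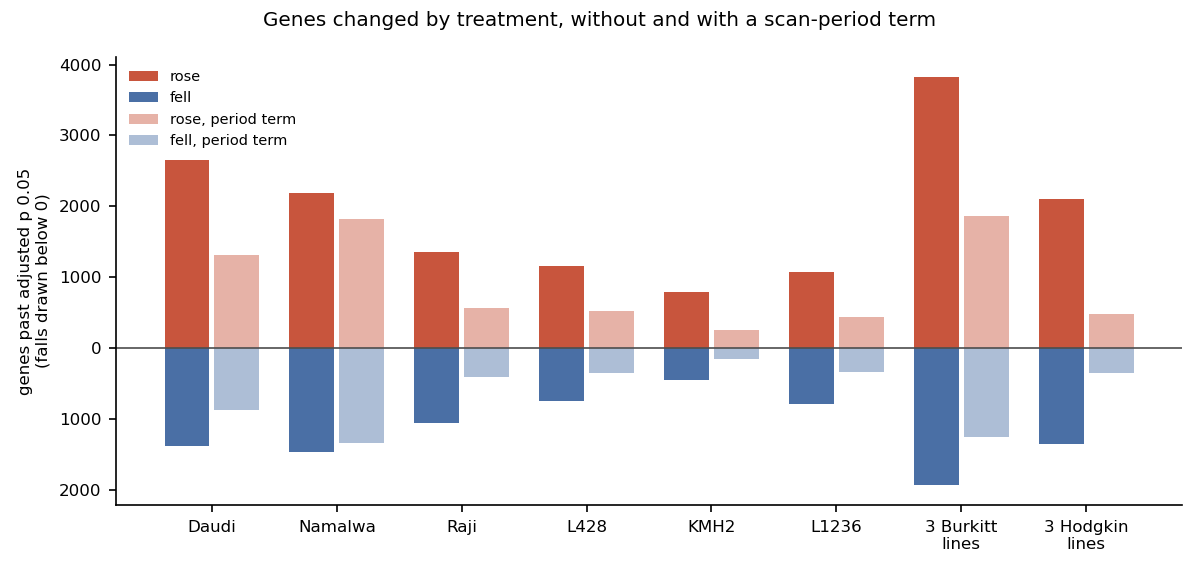
Genes that rose (above 0) and fell (below 0) on treatment in each line and over the 3 lines of each type, without and with a scan-period term. The 3 Burkitt lines had 3820 up and 1931 down without the term and 1859 up and 1262 down with it.

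Burkitt and Hodgkin responses differed in B-cell, germinal centre, plasma cell, Hodgkin-characteristic and MYC-related genes. The difference between the types' changes, tested as a contrast, was 6.83 for LGALS1 (SE 0.18), 4.82 for DHRS2, 4.79 for FSCN1, 3.21 for the extracellular matrix gene FBLN5 and 3.18 for HSPB1. It was -3.19 for PVRIG, -3.05 for PTPRCAP, -2.94 for the B-cell kinase BTK, -2.91 for CCL22 and -2.90 for CD79A. In all 1388 genes changed more upwards in Burkitt lines and 1010 more downwards, and with the line as the replicate only 19 genes passed. The B-cell identity list had 28 of 42 members lower in this contrast and 0 higher (29 lower alone; mean -1.20, camera adjusted p = 1.7e-18, 0.0164 with an estimated correlation, 0 and 26 with the period term), the Hodgkin-characteristic list 28 of 48 higher and 4 lower (29 and 5 alone; mean 0.85, 6.2e-07, 0.00408 with an estimated correlation, 25 and 3 with the period term), and the MYC and ribosome biogenesis list 16 of 33 lower (18 alone; mean -0.61, 3.14e-09, 0.0164 with an estimated correlation, 0 and 13 with the period term). Of 17 germinal centre genes 1 was higher and 10 lower (1 and 11 alone, mean -1.10, 1.23e-07, 0.0165 with an estimated correlation, 1 and 9 with the period term), and of 15 plasma cell genes 1 was higher and 8 lower (1 and 9 alone, mean -0.96, 9.93e-06, 0.0383 with an estimated correlation, 1 and 7 with the period term). MHC class II genes (10 higher, 2 lower of 13, mean 0.56, 0.00101, 10 and 2 with the period term), cell cycle genes (3 and 12 of 52, mean -0.30, 5.32e-05, 2 and 6 with the period term), ribosomal protein genes (3 and 0 of 44, 0 and 0 alone, mean 0.26, 0.0234, 1 and 0 with the period term) and unfolded protein response genes (5 and 8 of 29, 6 and 9 alone, mean -0.18, 0.0422, 3 and 5 with the period term) passed only with the preset correlation. With an estimated correlation their values were 0.125, 0.205, 0.657 and 0.0849. Interferon-stimulated (mean -0.21, 0.106, 8 and 5 with the period term), NF-kB target (0.38, 0.136, 16 and 5 with the period term) and cancer-testis genes (-0.08, 0.44, 5 and 1 with the period term) did not pass as lists. The types shared 1489 genes that rose (788.4 if unrelated) and 922 that fell (258.1 if unrelated). Their changes correlated at 0.605 over all genes with no array in common. Arrays of both types shared scan days and periods, however, and these values do not allow for an effect of these.

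**Figure D4:**
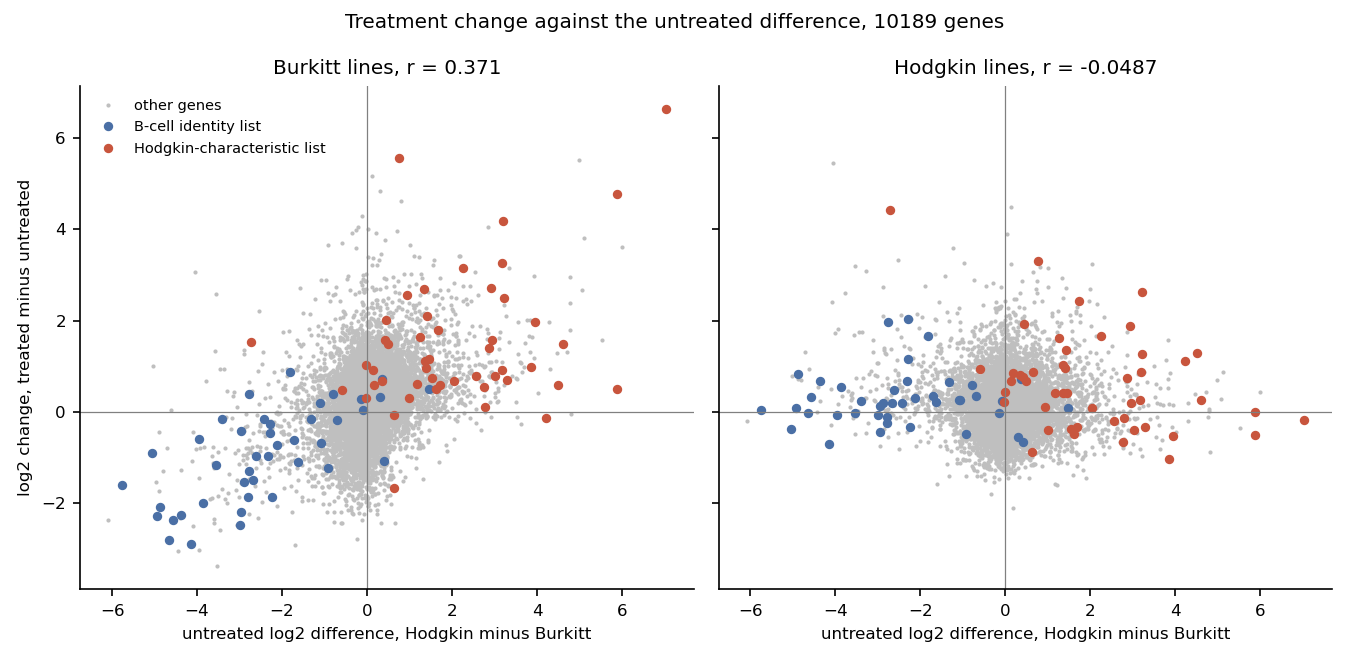
Log2 change on treatment (y axis) against the untreated log2 difference, Hodgkin minus Burkitt (x axis), for 10189 genes in Burkitt lines (r = 0.371) and Hodgkin lines (r = -0.0487). Coloured points are members of the B-cell identity and Hodgkin-characteristic lists.

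Genes higher in untreated Hodgkin lines tended to rise in treated Burkitt lines. Of the 73 genes higher in Hodgkin lines, 55 rose in Burkitt lines and 0 fell, among them LGALS1 and FSCN1, and of the 82 lower in Hodgkin lines 48 fell and 10 rose, among them CD79A, CD79B and SYK. If the calls were unrelated, 27.4 of the higher genes would have risen and 13.8 fallen, and 15.5 of the lower genes would have fallen and 30.7 risen. The untreated Burkitt arrays enter both calls, so genes chosen as low there tend to rise, and these values do not allow for that. Over all genes the Burkitt change correlated at 0.371 with the untreated difference (0.359 in Daudi, 0.320 in Namalwa, 0.290 in Raji). For this correlation 100 simulations in which treatment changed no gene gave a mean of 0.12 and a range of -0.0414 to 0.354. They hold only array noise, so they cannot judge real changes that are unrelated to the untreated difference. With the untreated arrays divided between the quantities the correlation was 0.313. In Hodgkin lines the correlation was -0.0487 (simulated mean -0.103, range -0.324 to 0.0809), which lies within the simulated range.

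**Figure D5:**
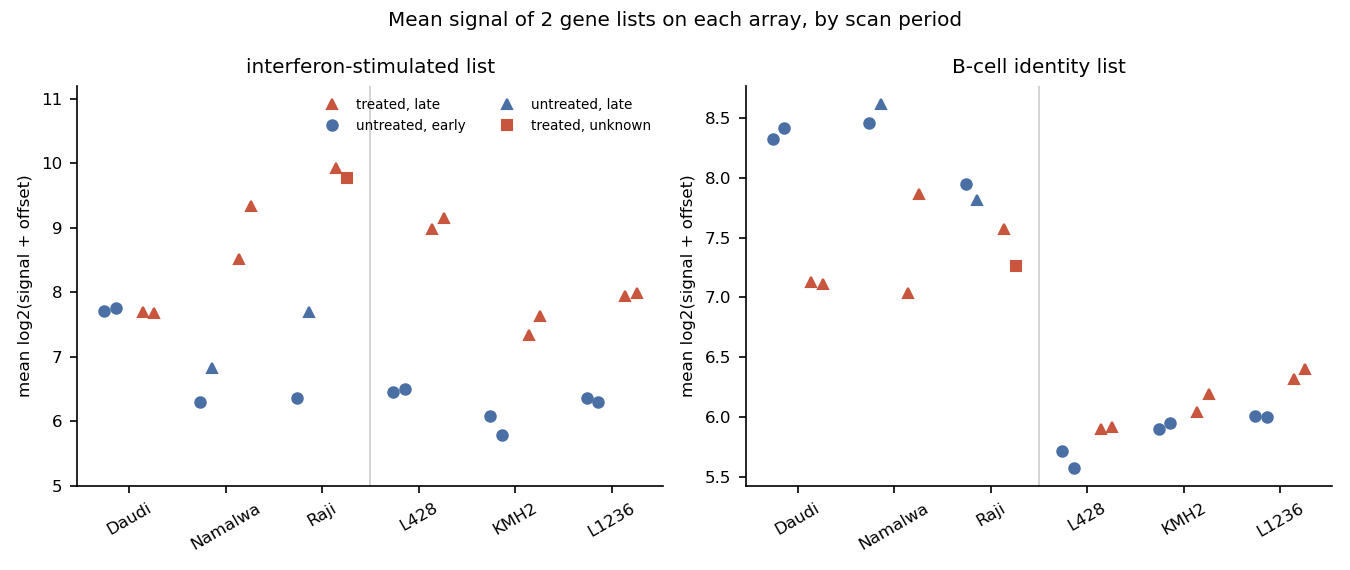
Mean log2(signal + offset) of the interferon-stimulated and B-cell identity lists on each array of the 6 lines, by treatment and scan period (symbols). The interferon-stimulated list was 6.37 on the early and 7.69 on the late untreated Raji array, and 9.93 and 9.77 on the treated ones.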

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

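The tests of the 3 patterns below were chosen after those patterns had been seen, and the outcomes that would count were written before each test was run, except for the scan-period tests of interferon-stimulated and B-cell identity genes, where they were written after. The result that stood out was the unlike response of Burkitt and Hodgkin lines, tested as a contrast of their changes with 2398 genes past the threshold against the spread of duplicate arrays, and 19 with the line as the replicate. Galectin 1 (LGALS1) led it with a difference of 6.83, followed by DHRS2 (4.82), FSCN1 (4.79), FBLN5 (3.21) and HSPB1 (3.18), which changed more upwards in Burkitt lines. PVRIG (-3.19), PTPRCAP (-3.05), the kinase BTK (-2.94), the chemokine CCL22 (-2.91) and the receptor chain CD79A (-2.90) changed more downwards there. The B-cell identity list differed by a mean of -1.20 and the Hodgkin-characteristic list by 0.849. Lines of a type also differed among themselves, for 1270 genes in the Burkitt lines and 655 in the Hodgkin lines. Apart from genes, Raji treated array 2 stood out through a CreX spike-in signal of 52.09 times its trimmed mean.

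Treated Burkitt lines moved towards the levels of untreated Hodgkin lines, as LGALS1 and FSCN1 did. The untreated Burkitt arrays enter both quantities, but with the difference taken from the other Burkitt lines the mean correlation was 0.248 (0.233 to 0.265 over 3 lines, SD 0.016). A general rise of weak genes and fall of strong ones was present (correlation of the change with the untreated Burkitt level -0.507), yet within 10 bins of that level the mean correlation with the Hodgkin level was 0.241 (0.15 to 0.351, SD 0.0627). Within the late scan period the correlation was 0.257 in Namalwa and 0.197 in Raji (1 treated against 1 untreated array). By these values neither shared arrays alone nor the scan period alone accounts for the pattern. The test in bins is weaker: the untreated Burkitt arrays set both the bins and the change, which by itself can give a positive correlation. The 3 explanations were not tested together. What moved these genes was not tested, and 5-aza-dC, TSA and cell stress cannot be told apart, since no array had 1 drug alone in these lines.

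Interferon-stimulated genes rose in treated Hodgkin lines (mean change 1.93, SE 0.201), but the scan period could explain part or all of this. In untreated Raji the late array exceeded the early one by 1.32 in this list, and in Namalwa by 0.521; the smallest Hodgkin change, 1.55 in KMH2, exceeded the larger of these by 0.226 (SE of 1 line 0.349). With the period term the list's change was 1.00 (SE 0.283). Over 10146 genes outside the list the late minus early difference correlated at only 0.0921 (SD over 3 lines 0.00791) with the Hodgkin change, and over the list at 0.346. On the 1 day with treated and untreated Namalwa arrays 43 of 43 members were higher in the treated one (mean 2.51). That is 1 array against 1, and members of a list are not replicates. The list's mean was 9.34 on that treated array and 8.52 on the other, beside 6.31 and 6.83 on the untreated ones. A real response in that Burkitt line is therefore likely, while for Hodgkin lines these tests cannot tell.

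B-cell identity genes such as CD79A, CD79B and SYK fell in treated Burkitt lines, while the list did not fall in Hodgkin lines. The list's mean log2 signal went from 8.33 and 8.42 to 7.13 and 7.11 on the Daudi arrays. On the Namalwa arrays it went from 8.46 and 8.62 to 7.04 and 7.86. The fall was smallest in Raji, from 7.95 and 7.81 to 7.57 and 7.26. Low Hodgkin levels could hide a fall, so the 13 members above the array median in untreated Hodgkin lines were taken alone. Their mean difference was still -0.913 (SE over members 0.276, 11 of 13 lower). Their mean change was -0.593 in Burkitt and 0.319 in Hodgkin lines. The list's mean of -0.935 lay below all 10000 random lists of the same untreated Burkitt levels (-0.515 to 0.332, median -0.11). Genes of these levels thus fell less on average than the list did. The random lists hold unrelated genes, while the list's members varied together (estimated correlation 0.16). Their range is therefore too narrow to judge chance, and the untreated Burkitt arrays set both the levels and the change. With the period term the mean was -0.887 (SE over the 42 members 0.163). Both of these SEs are spreads over genes measured on the same arrays. They hold no error between arrays or lines, and members of a list are not replicates. The cause of the fall was not tested, and the drugs, the days and the lymphoma type remain confounded in the contrast.

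For the treatment counts the real labels of the Burkitt arrays gave 5751 genes. The highest of the other splits, 100 in all with the real one, gave 4293 (2 of its 3 lines kept their real labels). For the Hodgkin arrays the values were 3465 and 1554. In each case 1 split, the real one, reached the real count. Most of the other possible splits mix treated and untreated arrays within at least 1 line, which raises the spread between duplicates. A few swap the labels of 1 whole line instead. That leaves the spread as it is but sets the change of that line against the others. For the Hodgkin arrays the real split is also the split by scan period. The splits therefore show that treated and untreated arrays differed, but not that treatment rather than scan period was the cause. For the untreated comparison (155 genes, highest other 1) and the difference of responses (2398, highest other 1279 with Daudi, Namalwa and KMH2 together), the 10 splits are too few.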

How the results depend on the processing

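The alternatives with a scan-period term, late or early arrays only, normalization-control scaling and 3 doubted arrays left out were chosen after the results were seen, and the other tests before. CD79A, CD79B, SYK, MYC and LGALS1 in Burkitt lines kept their calls with the period term and each line left out. Against a fold of 1.5, counts were 1399 in Daudi, 1410 in Namalwa, 572 in Raji, 412 in L428, 173 in KMH2, 354 in L1236, 1709 in Burkitt lines, 517 in Hodgkin lines, 346 for the difference of responses and 81 for the untreated comparison. With the line as the replicate they were 3166, 711 and 19 (Burkitt, Hodgkin, difference), so most genes of the difference rest on duplicate arrays. With the period term they were 2195 in Daudi, 966 in Raji, 876 in L428, 400 in KMH2, 774 in L1236, 3121 in Burkitt and 835 in Hodgkin lines, and 2731 on late arrays of Namalwa and Raji. The untreated comparison gave 522 genes with a replicate block, 604 with the line as a random block and 375 with the scan day as a block. Same-numbered treated and untreated arrays deviated together at -0.0723 (KMH2) to 0.15 (Namalwa, the only line over the set minimum of 0.1). Namalwa treated and untreated array 2 shared a scan day, and low values in the other lines do not show that samples were unpaired. With a replicate block 5771 Burkitt and 3385 Hodgkin genes passed. Without the 3 doubted arrays Raji had 1361. With 1 array or line left out, counts were 573 to 1370 in KMH2, 951 to 2054 in L1236, 968 to 2114 in L428, 1175 to 2609 in Raji and 62 to 227 untreated; a lone array is then assumed to vary like the other groups. The Burkitt correlation with the untreated difference was 0.324 with quantile scaling, 0.313 with split controls and 0.327 to 0.416 in leave-outs. The Hodgkin one was -0.0316 (quantile), -0.0652 (loess), -0.0747 (offset of 1), -0.0283 (offset at the 40th percentile), -0.034 (filter at the 60th), -0.031 (scan day random), -0.0186 (split controls), -0.128 (period term) and -0.108 to -0.03 in leave-outs, always near 0. The interferon-stimulated list in Burkitt lines had p = 0.139 by camera with an estimated correlation. Directions reversed for RPL14 in Burkitt lines (0.0102 with loess), POU2F2 in Burkitt lines (-0.423 as the mean of its probe sets), HLA-DQA1 in Hodgkin lines (0.754 with an offset of 1, another probe set) and HMGCS1 in Hodgkin lines (0.479 with the period term); the cause was not tested. Array signal near background compresses low genes, so falls of genes with weak untreated signal could be missed.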

Other observations

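The lists below were fixed beforehand, but the tests with a period term (members up and down) and with normalization-control scaling were chosen after the results were seen. Among lists of other cell types, the epithelial and stromal list and the myeloid and dendritic list rose in treated Burkitt lines with both correlations. The neuronal list passed only with the preset one, and the erythroid and megakaryocyte and the T-cell and NK lists did not pass. Weak genes rose in general in treated Burkitt lines (correlation of the change with the untreated Burkitt level -0.507). Camera does not match genes by level, and no level-matched lists were drawn here. The rises of these lists therefore cannot be told apart from that general rise. Of 20 epithelial and stromal genes 14 rose and 0 fell (16 rose adjusted over the list alone; mean 0.98, camera adjusted p = 0.00184, 0.0302 with an estimated correlation, 9 and 0 with the period term), among them the intermediate filament gene VIM (2.95) and the matrix genes FN1 (2.54) and COL6A3 (1.57). Of 25 neuronal genes 19 rose (20 alone; mean 0.98, 0.00059, 0.0598 with an estimated correlation; 6 with the period term), led by CHGA (3.22) and NEFH (2.62), and of 30 myeloid and dendritic genes 15 rose and 1 fell (mean 0.72, 0.0167, 0.0494 with an estimated correlation, 8 and 0 with the period term), with CST3 (2.08) and CTSB (1.93). With quantile scaling 10 epithelial, 12 neuronal and 10 myeloid genes rose. Of 11 erythroid and megakaryocyte genes 8 rose (mean 0.43, 0.258, 1 and 0 with the period term), but 1 rose and 1 fell with quantile and 2 rose and 1 fell with loess scaling. Of 30 T-cell and NK genes 11 rose and 2 fell (10 and 2 alone; mean 0.30, 0.641; the sign of this mean depended on scaling, from -0.05, with 5 up and 4 down, to 0.44, 2 and 3 with the period term), LCK falling (-1.44). Plasma cell genes fell in 8 of 15 cases and rose in 4 (mean -0.80, 0.00113, 0.0689 with an estimated correlation, 2 and 8 with the period term), JCHAIN (-2.37) and MZB1 (-3.39) among them. Imprinted genes rose in 9 of 17 cases and fell in 1 (mean 0.99, 0.036, 0.0818 with an estimated correlation, 7 and 2 with the period term), with PHLDA2 (3.82), CDKN1C (2.86) and MEG3 (1.90).

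Histone and deacetylase-inhibitor response genes rose in 20 of 23 cases in Burkitt lines and fell in 2 (mean 1.69, camera adjusted p = 5.18e-06, 0.0598 with an estimated correlation, 16 and 2 with the period term), led by the linker histone gene H1-2 (4.05) and H2BC5 (3.77). In Hodgkin lines, which had no TSA, 18 rose and 2 fell (mean 1.27, 2.86e-09, 0.0279 with an estimated correlation, 9 and 2 with the period term), with H4C8 (2.48). Of 13 MHC class II genes 9 rose and 1 fell in Burkitt lines (mean 0.55, camera adjusted p = 0.028, 0.228 with an estimated correlation, 6 and 0 with the period term), with HLA-DRB1 (1.33) and CD74 (0.78) up. The class II list thus passed only with the preset correlation. Of 13 MHC class I genes 7 rose and 2 fell (3 fell alone, mean 0.33, camera adjusted p = 0.328, 5 and 1 with the period term), with TAP1 (1.71) up and PSMB10 (-1.84) down. The class I list did not pass. The class I mean joins unlike lines: 0 rose and 5 fell in Daudi (mean -0.80, camera adjusted p = 0.00045, 0.0698 with an estimated correlation), 7 rose and 1 fell in Namalwa (mean 0.95, 0.00293, 0.0946 with an estimated correlation) and 9 rose and 1 fell in Raji (10 and 1 alone, mean 0.84, 0.000425, 0.0573 with an estimated correlation). With the period term they were 0 and 5, 6 and 0, and 5 and 0. Of 8 metallothionein genes 6 rose and 1 fell (mean 0.99, 0.0444, 0.308 with an estimated correlation, 6 and 0 with the period term), MT1X (1.75) among them. Of 27 p53 and DNA damage genes 20 rose and 4 fell (21 rose alone, mean 0.65, camera adjusted p = 0.0132, 0.037 with an estimated correlation, 13 and 3 with the period term), with TNFRSF10B (2.25). Of 26 methylation and acetylation machinery genes 5 rose and 9 fell (mean -0.18, camera adjusted p = 0.0132, 0.037 with an estimated correlation, 2 and 6 with the period term). With normalization-control scaling 7 of them rose and 8 fell, with a mean of -0.01, so this fall depended on scaling. DNMT1 (-0.94) and MBD2 (-1.50) fell, though not MBD2 as the mean of its probe sets (-0.29, limma adjusted p = 0.0925). Apoptosis (15 up, 5 down of 32, mean 0.48, 0.237, 12 and 3 with the period term), unfolded protein response (12 and 9 of 29, mean 0.25, 0.641, 7 and 5 with the period term), cholesterol synthesis (6 and 3 of 18, mean 0.16, 0.782, 5 and 3 with the period term) and ribosomal protein genes (3 and 1 of 44, 0 and 0 alone, mean 0.07, 0.433; -0.01 to 0.38 over scalings, 35 up and 0 down with loess, 0 and 0 with the period term) did not pass as lists.

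In Hodgkin lines neuronal genes rose in 13 of 25 cases (14 alone; mean 0.57, camera adjusted p = 0.00131, 0.0717 with an estimated correlation; 0 rose and 1 fell with the period term), AP-1 and immediate early genes in 18 of 30 with 1 fall (19 and 2 alone; mean 0.90, 2.07e-07, 0.0115 with an estimated correlation, 7 and 0 with the period term), with DUSP1 (2.43), and MHC class I genes in 8 of 13 with 1 fall (mean 0.46, 0.00364, 0.0944 with an estimated correlation; 1 rose with the period term). Myeloid genes rose in 9 of 30 cases (mean 0.41, 0.0201, 0.0509 with an estimated correlation, 2 and 0 with the period term), apoptosis genes in 9 of 32 with 1 fall (mean 0.35, 0.0347, 0.0824 with an estimated correlation, 3 and 0 with the period term) and unfolded protein response genes in 14 of 29 with 4 falls (15 and 6 alone; mean 0.43, 0.03, 0.0509 with an estimated correlation, 4 and 1 with the period term), with DDIT3 (1.92) and PPP1R15A (1.91). Calls that depended on scaling were those of cholesterol synthesis (2 up, 7 down of 18, mean -0.20, 0.03, 0.0509 with an estimated correlation; -0.23 to 0.04 over scalings, 4 and 2 with normalization-control scaling, 1 and 3 with the period term), machinery (4 and 7 of 26, 7 and 7 alone, mean -0.12, 0.0388, 0.0559 with an estimated correlation; -0.20 to 0.11 over scalings, 9 and 5 with normalization-control scaling, 1 and 3 with the period term) and ribosomal protein genes (0 and 8 of 44, 0 and 4 alone, mean -0.19, 3.93e-05, 0.462 with an estimated correlation; -0.19 to 0.11 over scalings, 6 and 0 with loess, 3 and 1 with quantile and 4 and 0 with normalization-control scaling, 0 and 0 with the period term). HDAC1 fell (-1.15), as did DNMT1 (-0.75, limma adjusted p = 0.0991 with the period term). Epithelial (9 up, 2 down of 20, mean 0.47, 0.0526, 3 and 1 with the period term), imprinted (8 and 0 of 17, 0.45, 0.0526, 1 and 0 with the period term), T-cell and NK (5 and 0 of 30, 0.28, 0.218, 1 and 0 with the period term), plasma cell (4 and 2 of 15, 0.16, 0.839, 0 and 0 with the period term), erythroid (1 and 0 of 11, 0.19, 0.561, 0 and 0 with the period term), metallothionein (2 and 0 of 8, 1 and 0 alone, 0.38, 0.236, 0 and 0 with the period term) and MHC class II genes (3 and 5 of 13, -0.01, 0.308; -0.01 to 0.23 over scalings, 2 and 0 with the period term) did not pass as lists. The class II mean joins falls in L428 (1 up, 5 down, 2 and 7 alone, mean -0.34, camera adjusted p = 0.0088, 0.166 with an estimated correlation) and KMH2 (0 and 3, 1 and 3 alone, mean -0.36, 0.00536, 0.155 with an estimated correlation) with rises in L1236 (4 and 0, 5 and 0 alone, mean 0.68, 0.00459, 0.127 with an estimated correlation). With the period term these were 1 and 3, 0 and 0, and 4 and 0.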
